A study of Mus musculus with 8 samples.

How the data were processed

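The study measured RNA of RAW264.7 cells on 8 two-colour Agilent mouse arrays of 41174 probes, 1 per bacterium (L. acidophilus or B. clausii) and time (1, 2, 4 or 6 h). Per the labels, treated RNA carried Cy5 and time-matched untreated RNA Cy3 on all 8, and per the series design text the RNA of 3 cultures was pooled in equal amounts. No array exchanged the dyes. Slide, scan and annotation version coincide with the bacterium, and the position on the slide with the time.

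Per the file headers, the deposited spot intensity values are foreground means and local background medians in each channel, and the processed intensities were background-subtracted, detrended and dye-normalized (linear and LOWESS) by Feature Extraction. The headers give version 10.7.3.1 of that software and the labels' processing notes 10.5.1.1. The deposited log10 ratios were computed by Feature Extraction, per the file headers, as log10 of red over green processed signal, and the series matrix holds the same values rounded, as a comparison with the array files showed (r of 0.999999 on all 8 arrays and differences under 0.005). Between 25.2% and 35.1% of them are exactly 0. The files also hold 0 or 1 flags per spot.

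Ratios were computed anew from the mean foreground and median background. Local backgrounds above 3 times the median of the array that Feature Extraction had itself marked as outliers were set to that median and their spots left out, because extreme backgrounds can upset the normexp fit. This repair was added after the files had been seen. Background was corrected with normexp (offset 50) and log2 ratios were normalized by loess within each array in limma 3.58.1 with statmod 1.5.0 and data.table (1.17.8) in R 4.3.3. Flagged spots, 0.473% to 0.890% per array, were left out and replicate spots averaged, which left 549 probes without an unflagged spot on some array. Probes were named through a reference gene table of assembly GRCm38.p6, 27668 by RefSeq accession, 85 by another accession of the probe and 5993 by symbol or synonym. The other 7428 kept the name of the file, and 1873 names differ between the annotation versions of the 2 slides. Probes well above background in at least 1 channel on at least 2 arrays were kept (21273), and each of the 14807 genes was represented by its brightest probe, of which 12414 have a usable symbol and 4822 more than 1 kept probe.

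Single arrays have no replicate, so their genes were described by a rule of at least 2-fold (3-fold as the alternative). Where a gene was well above background in 1 channel only, its weaker signal was raised to the lowest detected signal of that channel where it lay below. The ratio is then an approximate lower bound, and otherwise it is the measured ratio. Limma (lmFit, eBayes, Benjamini-Hochberg, adjusted p under 0.05) fitted bacterium and time to the 8 arrays with 3 residual degrees of freedom (prior 5.80, prior SD 0.0938), for the mean response to each bacterium, their difference, and the change from 1 and 2 h to 4 and 6 h. The interaction of bacterium and phase came from a fit of the 4 cells with 4 residual degrees of freedom (prior 6.38, prior SD 0.126) that did not pair the arrays of a time. The spread in the first fit is the disagreement of the bacteria within times, with scatter between times removed, and neither fit holds scatter between cultures. Camera, with a preset correlation of 0.01 between genes, tested 39 of 40 gene lists for a shift against the other genes, and 1 list had fewer than 3 measured genes. Values after ± are standard errors of the limma fit unless called SD.

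The genes named were chosen by a fixed rule: for each contrast the 10 called genes with the largest change in each direction that have a symbol and the same sign in every array entering, or, where none passed, the 5 with the smallest p in each direction as values only. For each array up to 6 genes past 2-fold at each end and up to 3 bounds at each end were eligible, along with a panel of 25 macrophage genes and the top genes of each called list. The comparisons with their limma and camera tests, the lists, panel and naming rule and most alternatives were fixed before the data were examined.

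The alternatives were the processed signals, the series matrix values, a normexp offset of 0, no background correction, median centring, scaling between arrays, no filter or a filter on both channels of all 8 arrays, the mean over probes, no time term, a trended robust prior, adjusted p under 0.1, the treated channel alone, an estimated correlation in camera, fry, and leaving out each array or time. Local background as deposited, scaling to the spike-in controls and an interaction with time as a block were chosen after seeing the data. The difference of the spike-in controls was tested by exact permutation. The scripts were tested on simulated data of 14807 genes with 200 changed, 5 times per contrast. They recovered 98.6% to 99.6% of changes of 0.5 log2 and 100% of those of 1 log2, with 7.35% to 8.10% false genes among the calls, above the nominal 5%, and 4.10% of list tests under p 0.05 where nothing changed. The simulated genes varied independently, so the share of list tests does not cover lists whose genes vary together. Interactions of 0.5 log2 were recovered in 34.4% and those of 1 log2 in 99.2%, with 9.12% false genes among the calls, and with time as a block in 34.0% and 100%, with 13.4% false. The simulated spread was that of the first fit (prior SD 0.0938). It lacked the scatter between times of a phase that the fit of the 4 cells holds (prior SD 0.126). Recovery by the fit of the 4 cells is therefore overstated.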

Results

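RAW264.7 cells, a mouse macrophage-like line, were exposed to Lactobacillus acidophilus MTCC-10307 or to Bacillus clausii MTCC-8326 (L. acidophilus and B. clausii from here on) at 100 bacteria per cell, and RNA was taken after 1, 2, 4 and 6 h. Each of the 8 arrays set treated RNA (Cy5) against RNA of time-matched untreated cells (Cy3), so every value below is a log2 ratio of treated to untreated cells. RNA of 3 cultures was pooled in equal amounts before labelling, which leaves 1 array per bacterium and time and no replicate of any single array. The title of the series gives the aim as the kinetics of expression after treatment with potential probiotic strains.

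Between 42.0% and 47.4% of the 41174 probes were well above background in the untreated channel, and between 39.6% and 51.5% in the treated channel. The lowest treated share was on the 1 h B. clausii array (39.6%) and the highest on the 2 h L. acidophilus array (51.5%). No spot was saturated. Replicate spots of the same probe had a median SD of 0.0931 to 0.134 log2 on the L. acidophilus arrays and of 0.0939 to 0.168 on the B. clausii arrays. After probes that stayed dim were left out, 14807 genes were tested. Their ratios had an SD over genes of 0.21 to 0.26 (L. acidophilus) and 0.23 to 0.30 (B. clausii), so most genes differed little between the channels in this processing. With the scanner software's processed signals the SD was 0.39 to 0.47 and 0.46 to 0.57.

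At 1 h the chemokine gene Cxcl2, which attracts neutrophils, had the highest ratio with both bacteria, 2.06 (4.18-fold) with L. acidophilus and 2.35 (5.10-fold) with B. clausii. Adm, which encodes adrenomedullin, followed at 1.97 and 2.09, and the monocyte chemokine gene Ccl2 stood at 1.37 and 1.48. At 2 h the L. acidophilus array was led by Cxcl2 (1.84), Ccl2 (1.78), Adm (1.43) and Ccl7 (1.23), and the B. clausii array by Ccl2 (1.42), Adm (1.42), Ankrd37 (1.35) and Ddit4 (1.33). From 4 h the leading genes among those with a usable symbol and signal in both channels were others. With L. acidophilus they were Dpp7 (1.54), Bhlhe40 (1.33) and Slc43a2 (1.30) at 4 h and Skil (1.56) and Tnfsf13b (1.52) at 6 h. With B. clausii they were the paraspeckle RNA Neat1 (1.43), Lrrk1 (1.35) and Slc43a2 (1.24) at 4 h, and Slc3a2 (1.64), Slc43a2 (1.58) and H1f0 (1.56) at 6 h.

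By the same limits, the lowest ratios belonged to less familiar genes. With L. acidophilus they were Cst10 (-1.28) at 1 h, Arc (-1.12) at 2 h, Chac1 (-1.44) and the receptor adaptor gene Traf1 (-1.08) at 4 h, and Psmd2 (-1.36) and Lpin1 (-1.35) at 6 h. B. clausii gave Rhox5 (-1.33) and Ppig (-1.20) at 1 h, Ccar1 (-1.14) at 2 h, Brd8 (-2.07) and Ccar1 (-1.56) at 4 h, and Selenbp1 (-1.51) and Glg1 (-1.49) at 6 h. Genes well above background in the treated channel only were at least 2.60-fold (Zc3h3) and 2.42-fold (Chrnb2) higher in treated cells at 1 h with B. clausii. Genes seen in the untreated channel only stood 2.41-fold (Rp1l1, 1 h B. clausii) and 2.34-fold (Bean1, 6 h L. acidophilus) higher in untreated cells. The values of Rp1l1 and Bean1 are the measured ratios, with an undetected treated signal, and are not lower bounds. Those of Zc3h3 and Chrnb2 are approximate lower bounds. All of these values are open to dye bias.

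By the rule of at least 2-fold, 58 genes were higher and 31 lower at some time with L. acidophilus, and 117 and 81 with B. clausii. Ccl2 alone passed at all 4 times with L. acidophilus. Lrrk1 and Neat1 (higher) and Ppig (lower) did so with B. clausii, and Herpud1 and Klf2 were 2-fold higher at one time and 2-fold lower at another. The genes past 2-fold numbered 29, 11, 19 and 44 at 1, 2, 4 and 6 h with L. acidophilus and 89, 27, 45 and 90 with B. clausii. The 1 h and 6 h B. clausii arrays, with the most such genes, also had the widest replicate spots. Their median SD was 0.167 and 0.168 log2, against 0.0983 and 0.0939 at 2 and 4 h with B. clausii. The scanner software's own processed signals gave 636, 433, 427 and 719, and 1015, 690, 714 and 877. No test is possible on single arrays.

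Over the 4 times, L. acidophilus raised the monocyte chemokine genes Ccl2 (mean log2 ratio 1.40 ± 0.13, SE, adjusted p = 2.11e-04) and Ccl7 (1.02 ± 0.15, adjusted p = 0.00143). Neat1 (1.12 ± 0.05, adjusted p = 3.8e-05) and the kinase gene Lrrk1 (1.05 ± 0.05, adjusted p = 3.8e-05) rose too. Further rises were those of the amino-acid transporter gene Slc43a2 (0.96), Trpc2 (0.91), Gdap10 (0.87), urokinase (Plau, 0.84), the cyclin gene Ccnt2 (0.82) and the transcriptional repressor gene Bhlhe40 (0.82). The largest falls were smaller, led by Cracdl (-0.83 ± 0.05, adjusted p = 6.09e-05), the selenium-binding protein gene Selenbp1 (-0.81 ± 0.08, adjusted p = 2.51e-04), Crtam (-0.75) and Traf1 (-0.75). Arc (-0.72), Angpt2 (-0.71), Agmo (-0.70), Btg1 (-0.69), the autophagy gene Gabarap (-0.68) and Rab15 (-0.67) followed. All these genes had 1 sign in all 4 arrays, which a constant dye effect would also give.

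In the limma fit 6247 genes changed on average with L. acidophilus, 3513 higher and 2734 lower (1338 and 4494 with median centring, 1052 and 1277 with the local background as deposited), and 5 of them (Ccl2, Cxcl2, Neat1, Lrrk1 and Ccl7) rose and 0 fell at least 2-fold. Without the 1 h, 2 h or 4 h L. acidophilus array the fit called 4095, 3583 and 3237 genes. The spread behind these p-values is the disagreement of the bacteria within times, with 3 residual degrees of freedom, and does not hold scatter between times, dye effects or the noise of an untreated pool that both bacteria may have shared. Averaged over all their probes, the changes were smaller for Lrrk1 (0.34), Ccnt2 (0.35), Slc43a2 (0.41), Plau (0.53) and Trpc2 (0.53), and with the processed signals Cracdl stood at -1.64.

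Among the gene lists fixed beforehand, ribosomal protein genes such as Rplp1 (0.80 ± 0.05), Rpl32 (0.64), Rps18 (0.63) and Rpl5 (0.63) rose with L. acidophilus. Of the 30 measured, 21 rose, 0 fell and 9 did not pass, or 21 and 1 adjusted over the list alone, with a mean of 0.30 (camera, adjusted p = 1.26e-06, and adjusted p = 0.649 with an estimated correlation). This shift over other genes, 0.28, was 0.01 with the scanner's processed signals (adjusted p = 0.550), which ends the call. Chemokine genes had a mean of 0.42, and of 11 measured 8 rose (Ccl2, Cxcl2 at 1.13 ± 0.13, Ccl7 and Cxcl14 at 0.29), 1 fell and 2 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.0313, and adjusted p = 0.649 with an estimated correlation). Of 10 extracellular matrix protease and coagulation genes 7 rose, among them Plau, Adam8 (0.35) and Adamts1 (0.30), 0 fell and 3 did not pass, or 8 and 0 adjusted over the list alone (mean 0.26, adjusted p = 0.0174, and adjusted p = 0.649 with an estimated correlation). The protease call ended without both 1 h arrays (adjusted p = 0.121) or both 2 h arrays (adjusted p = 0.0774), without the time term (adjusted p = 0.148) or with the local background as deposited (adjusted p = 0.0878). The chemokine call held in 13 of 24 alternatives and ended with the processed signals (adjusted p = 0.167), a normexp offset of 0 (0.0861), no background correction (0.0542), no filter on dim probes (0.0545) or no time term (0.192), and without the L. acidophilus array of 4 h (adjusted p = 0.0574) or 6 h (adjusted p = 0.0836), both 1 h arrays (adjusted p = 0.150) or both 2 h arrays (adjusted p = 0.236).

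With B. clausii many of the same genes were higher in treated cells. Treated RNA was in Cy5 on every array, so a gene-specific dye effect cannot be told apart from a shared rise. Neat1 rose most (1.37 ± 0.05, adjusted p = 8.06e-06), followed by the hypoxia-induced gene Ankrd37 (1.22 ± 0.09, adjusted p = 2.85e-05), Lrrk1 (1.18 ± 0.05, adjusted p = 1.25e-05), Adm (1.13 ± 0.07, adjusted p = 2.02e-05) and Plau (1.09 ± 0.06, adjusted p = 1.34e-05). Slc43a2 (1.07), Trpc2 (1.02), the Toll-like receptor homologue gene Cd180 (0.99), lymphotoxin beta (Ltb, 0.99) and the mTORC1 inhibitor gene Ddit4 (0.96) came next. The falls were headed by Ccar1 (-1.26 ± 0.06, adjusted p = 1.33e-05), Sltm (-1.18 ± 0.07, adjusted p = 1.54e-05) and the peptidyl-prolyl isomerase gene Ppig (-1.15 ± 0.06, adjusted p = 1.34e-05). Esf1 (-1.12), Heatr6 (-1.08), the 7SK RNA-binding protein gene Larp7 (-1.06), Glg1 (-1.03), the kinase gene Rock1 (-1.02), Rtf1 (-0.98) and Rrp1 (-0.97) also fell.

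With B. clausii 6541 genes changed, 3413 higher and 3128 lower (841 and 8662 with median centring, 1376 and 2210 with the local background as deposited). Of these 10 rose and 8 fell at least 2-fold, and 4644 of the 6541 had 1 sign in all 4 arrays. The count was 4198 without the 2 h and 3953 without the 4 h B. clausii array. Averaged over all their probes Lrrk1 stood at 0.31, Slc43a2 at 0.41, Cd180 at 0.51, Trpc2 at 0.58, Plau at 0.68, Heatr6 at -0.50, Rtf1 at -0.49, Larp7 at -0.65, Ccar1 at -0.68 and Sltm at -0.72, all still past the threshold. Median centring in place of loess moved the median of all genes to -0.46 at 1 h and -0.25 at 2 h with B. clausii, from 0.00 and 0.01, and left Ddit4 at 0.50, Plau at 0.63, Trpc2 at 0.64, Adm at 0.67, Ankrd37 at 0.77, Lrrk1 at 0.78 and Neat1 at 0.91. Changes in this text are therefore relative to the typical gene of each array at that brightness.

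The ER chaperone genes Pdia6 (0.73 ± 0.04), Hspa5 (0.69 ± 0.06), Hsp90b1 (0.61) and Manf (0.55) rose with B. clausii, and of the 17 unfolded protein response genes 14 rose, 1 fell and 2 did not pass, or 15 and 1 adjusted over the list alone (mean 0.28, adjusted p = 3.04e-04, and adjusted p = 0.412 with an estimated correlation). Matrix protease and coagulation genes had 9 rises, 0 falls and 1 not passed, or 9 and 0 adjusted over the list alone (mean 0.39, adjusted p = 3.04e-04, and adjusted p = 0.412 with an estimated correlation), with Plau, Adamts1 at 0.48 and Adam8 at 0.46. Ribosomal protein genes, led by Rplp1 (0.82) and Rps19 (0.67), had 20 rises, 1 fall and 9 not passed, or 21 and 1 adjusted over the list alone (mean 0.28, adjusted p = 2.57e-05, and adjusted p = 0.412 with an estimated correlation), and their shift of 0.27 over other genes was 0.00 with the processed signals (adjusted p = 0.649). Phagocytic receptor genes, among them the integrin gene Itgb2 (0.62), Fcgr4 (0.59) and Msr1 (0.43), had 8 rises, 0 falls and 6 not passed, or 8 and 0 adjusted over the list alone (mean 0.21, adjusted p = 0.0174, and adjusted p = 0.442 with an estimated correlation).

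Hypoxia and glycolysis genes also shifted up with B. clausii, with Ankrd37, the glycolytic regulator gene Pfkfb3 (0.84), the glucose transporter gene Slc2a1 (0.79) and pyruvate kinase (Pkm, 0.56) in front. Of 24, 12 rose, 2 fell and 10 did not pass, with the same counts adjusted over the list alone (mean 0.23, adjusted p = 0.0174, and adjusted p = 0.512 with an estimated correlation). Chemokine genes had 7 rises (Ccl2 at 0.82 ± 0.13, Ccl7 at 0.57, Cxcl2 at 0.55 and Ccl9 at 0.44), 0 falls and 4 not passed, or 7 and 1 adjusted over the list alone (mean 0.30, adjusted p = 0.0223, and adjusted p = 0.586 with an estimated correlation). Antigen presentation genes had 12 rises (Cd83 at 0.44, the invariant chain gene Cd74 at 0.44 and H2-Ab1 at 0.42), 2 falls and 6 not passed, with the same counts adjusted over the list alone (mean 0.16, adjusted p = 0.0445, and adjusted p = 0.586 with an estimated correlation). The chemokine call ended without the 1 h B. clausii array (adjusted p = 0.0974), both 1 h arrays (0.478) or both 2 h arrays (0.156), and the phagocytic receptor and hypoxia calls ended without both 1 h arrays (0.0593 and 0.171) or both 2 h arrays (0.0559 and 0.0764). The antigen presentation call ended without the L. acidophilus array of 1 h (p just above the threshold) or 4 h (0.0509), both 2 h arrays (0.0764) or both 4 h arrays (0.0593). Median centring ended all the B. clausii calls except those of the ribosomal and protease genes, the processed signals ended those of the phagocytic receptor (0.0579), hypoxia (0.281), chemokine (0.0647) and antigen presentation genes (0.0647), a normexp offset of 0 ended those of the hypoxia (0.0708) and antigen presentation genes (0.0795), leaving out the time term ended those of the hypoxia (0.111) and chemokine genes (0.0751), and the estimated correlation ended every list call of all 4 comparisons.

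The responses to the 2 bacteria were compared gene by gene. Across 14807 genes, which are not independent replicates, the ratios of L. acidophilus and B. clausii at the same time had Pearson's r of 0.71, 0.78, 0.71 and 0.64 at 1, 2, 4 and 6 h. Arrays of different times gave 0.08 to 0.67 across the bacteria and up to 0.74 within a bacterium (1 and 2 h L. acidophilus). The covariances at the same time were 0.0488, 0.0381, 0.0373 and 0.0496. Whether both bacteria were set against the same untreated pool is not given in the sources used here. A shared pool alone gave r of 0.50 in simulation, so part of these values can come from it. That 0.50 follows from giving every pool the same variance and was not fitted to these arrays. Called genes overlapped at 2193 higher (810 for independent lists) and 1809 lower (578), and 42 had opposite signs, but the numbers for independent lists leave out any shared untreated pool and the dye orientation common to all arrays. They also leave out that both calls use the same spread of each gene, so genes with a small spread pass more readily in both.

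The bacteria differed most in genes that fell with B. clausii alone or more strongly than with L. acidophilus. Rock1 stood at -0.18, -0.17, -0.24 and -0.21 at 1, 2, 4 and 6 h with L. acidophilus and at -1.11, -0.96, -1.24 and -0.76 with B. clausii (L. acidophilus minus B. clausii 0.82 ± 0.08, adjusted p = 0.0176). Ccar1 (0.79 ± 0.08, adjusted p = 0.0176), Sltm (0.79 ± 0.10, adjusted p = 0.0196) and Ppig (0.77 ± 0.08, adjusted p = 0.0176) differed in the same way, as did Esf1 (0.75), Heatr6 (0.71), Glg1 (0.70), Larp7 (0.70), Rtf1 (0.68) and the kinesin gene Kif5b (0.66). In the other direction the progranulin gene Grn differed by -0.70 ± 0.09 (adjusted p = 0.0196), with -0.64, -0.37, -0.73 and -0.42 for L. acidophilus and 0.29, 0.01, -0.04 and 0.37 for B. clausii. Cd74 differed by -0.55 ± 0.08 (adjusted p = 0.0338), at 0.35 to 0.55 with B. clausii and -0.37 to 0.03 with L. acidophilus. Ptprz1 (-0.54), the spliceosome gene Prpf8 (-0.48), the potassium channel gene Kcnn4 (-0.45), Fxyd2 (-0.44), gamma actin (Actg1, -0.43), the integrin gene Itga5 (-0.41), Tmem176b (-0.41) and the Fc receptor gene Fcgr3 (-0.39) completed the list.

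The limma contrast of L. acidophilus and B. clausii called 95 genes, 66 higher and 29 lower with L. acidophilus (4852 and 83 with median centring, 12 and 14410 with scaling to the spike-in controls), 0 of them by 2-fold, against 3361 at an unadjusted p under 0.05. All 4 L. acidophilus arrays lay on 1 slide and all 4 B. clausii arrays on another, so slide and bacterium cannot be told apart. Leaving out either 1 h array, which removes that time from the contrast, gave 15 genes, either 2 h array 0, either 4 h array 0 and either 6 h array 3. With the processed signals or a normexp offset of 0 the count was 0. Averaged over probes Rock1 (0.47), Ccar1 (0.48), Sltm (0.45), Esf1 (0.49) and Larp7 (0.44) still passed, whereas Heatr6 (0.34), Rtf1 (0.30), Glg1 (0.41), Kif5b (0.41) and Actg1 (-0.28) did not.

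Hypoxia and glycolysis genes had a mean difference of -0.12, lower with L. acidophilus (camera, adjusted p = 0.00628, and adjusted p = 0.529 with an estimated correlation). Of 24, 0 rose, 0 fell and 24 did not pass, or 0 and 4 adjusted over the list alone, with Ankrd37 at -0.62 ± 0.12, Gapdh at -0.40 and Pkm at -0.31. Among 14 phagocytic receptor genes 0 rose, 2 fell (Fcgr3 and Itgb2, -0.39 each) and 12 did not pass, or 0 and 4 adjusted over the list alone (mean -0.14, adjusted p = 0.00628, and adjusted p = 0.529 with an estimated correlation). The 17 ER chaperone genes had a mean of -0.10 (adjusted p = 0.00628, and adjusted p = 0.529 with an estimated correlation), which turned to a shift of 0.03 with median centring. Of these 0 rose, 0 fell and 17 did not pass, or 1 and 2 adjusted over the list alone, and Dnajb9 stood at 0.34, Sdf2l1 at -0.26 and Calr at -0.24. The list of liver X receptor targets and lipid efflux genes (Scd2 -0.33, Abca1 -0.29 and Srebf1 -0.28) had 0 rises, 0 falls and 13 not passed, or 1 and 5 adjusted over the list alone (mean -0.13, adjusted p = 0.00941, and adjusted p = 0.614 with an estimated correlation).

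Antigen presentation genes were lower with L. acidophilus as well, with Cd74 the only fall, 0 rises and 19 not passed, or 0 and 3 adjusted over the list alone (mean -0.10, adjusted p = 0.0103, and adjusted p = 0.614 with an estimated correlation), and with H2-D1 at -0.34 and H2-Eb1 at -0.29. Protease and coagulation genes (Mmp9 -0.30, Timp2 -0.26) had 0 rises, 0 falls and 10 not passed, or 0 and 4 adjusted over the list alone (mean -0.12, adjusted p = 0.0284, and adjusted p = 0.529 with an estimated correlation). The integrated stress response genes (Slc3a2 -0.66 ± 0.22, Chac1 0.47, Ddit4 -0.34) had 0 rises, 0 falls and 19 not passed, or 1 and 3 adjusted over the list alone (mean -0.08, adjusted p = 0.0324, and adjusted p = 0.529 with an estimated correlation). These last calls, of the proteases and of the stress response, ended without either 1 h array (adjusted p = 0.110 each) with the processed signals (adjusted p = 0.116 each), with a normexp offset of 0 (0.0666 and 0.0554) or without background correction (0.141 and 0.0529), and the stress response call with the stricter filter (0.0838). They and the ER chaperone call ended without the time term (adjusted p = 0.107 each), and the ER chaperone call with the mean over probes (0.0565). Median centring ended each of the 7 list calls except that of the phagocytic receptors, and scaling to the spike-in controls left none of the 7 and called the chemokine genes alone, higher with L. acidophilus. That scaling moves every gene alike, so the shift of each list over other genes did not change. It stayed at -0.13 for the hypoxia genes and -0.15 for the phagocytic receptors.

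Spike-in control RNAs, whose amounts are not given in the sources used here, shifted between the bacteria too. Relative to the mean of each control over all arrays, the 10 controls had a mean log2 deviation of 0.22 ± 0.05 (SD, n = 4) on the L. acidophilus arrays and -0.22 ± 0.08 (SD, n = 4) on the B. clausii arrays. The difference of 0.449 (1.37-fold) had p = 0.0286 in a two-sided exact permutation test, the smallest that 4 against 4 arrays allow. That test exchanged the arrays freely and ignored that they are paired by time. Each bacterium lay on its own slide, so the arrays are not independent and the p-value cannot separate bacterium from slide. After loess the spike-ins lay at mean ratios of -0.12 and -0.57.

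**Figure D1:**
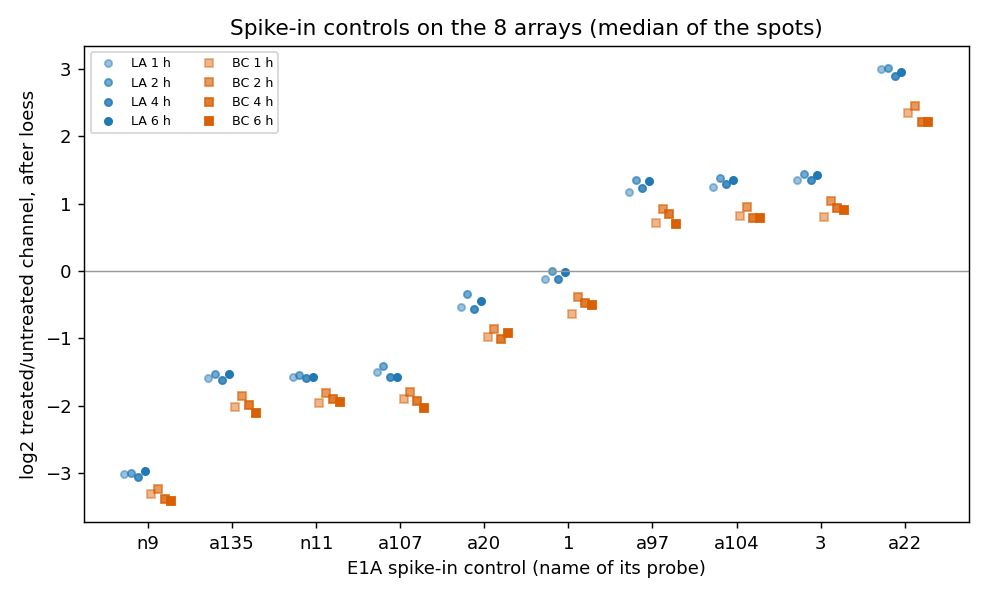
Log2 ratio of treated to untreated signal after loess (vertical axis) for each of the 10 spike-in controls (horizontal axis), with 1 point per array, circles for L. acidophilus (LA) and squares for B. clausii (BC). The mean over controls is -0.12 on the L. acidophilus arrays and -0.57 on the B. clausii arrays.

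Some chemokine genes fell with time. Cxcl2 fell by 1.96 ± 0.18 from the mean of 1 and 2 h to the mean of 4 and 6 h, averaged over both bacteria (adjusted p = 4.2e-04), and the macrophage chemokine gene Ccl4 fell by 1.81 ± 0.06 (adjusted p = 2.64e-06). Herpud1, of ER-associated degradation, fell by 1.72 ± 0.06 (adjusted p = 3.22e-06), Adm by 1.48 ± 0.10 (adjusted p = 1.34e-04), Chac1 by 1.35 ± 0.19 (adjusted p = 0.00221), Trib1 by 1.19, the stress factor gene Ddit3 by 1.16, Msmo1 of cholesterol synthesis by 1.14 and Maff by 1.11. The ratio of Ccl3 fell by 1.42 ± 0.10 (adjusted p = 1.73e-04), but its signal in untreated cells rose by 1.05 while that in treated cells changed by -0.38, whereas for Cxcl2 the treated channel changed by -1.94 and the untreated channel by 0.02. Later rises were those of Mllt11 (1.33 ± 0.06, adjusted p = 3.12e-05), the pro-apoptotic BH3 gene Bmf (1.23 ± 0.12, adjusted p = 4.55e-04), Esyt3 (1.18), Tmem268 (1.11), Phf13 (1.01), Armc7 (0.97), the carnitine palmitoyltransferase gene Cpt1a (0.94), Bbs4 (0.91), Enc1 (0.90) and Rasa4 (0.87).

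In all, 3639 genes changed between the early and the late times, 1812 up and 1827 down (2902 and 383 with median centring, 2390 and 1196 with scaling to the spike-in controls), of which 5 rose and 12 fell at least 2-fold. The changes of the bacteria, taken apart, had r of 0.74 across genes and the same sign in 73.6% of genes. With no effect, shared untreated pools and equal variances, simulation gave 0.501 and 66.7%, so part of this can come from such pools. The simulated values were not fitted to these arrays. Time coincides with position on the slide, and the spread in this fit does not hold scatter between times of a phase. The count was 1766 without the 2 h L. acidophilus array, 1782 without that of 4 h, 2163, 2108 and 1909 without the B. clausii array of 1, 2 and 4 h, 1141 without both 1 h arrays and 1197 without both 6 h arrays. The calls of Chac1 with the processed signals (-1.53, adjusted p = 0.0602) and of Cxcl2 (-1.27, adjusted p = 0.0927) and Enc1 (0.54, adjusted p = 0.0524) with the local background as deposited were lost. Averaged over probes, Bmf stood at 0.66, Phf13 at 0.61, Bbs4 at 0.56, Cpt1a at 0.55 and Enc1 at 0.52.

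**Figure D2:**
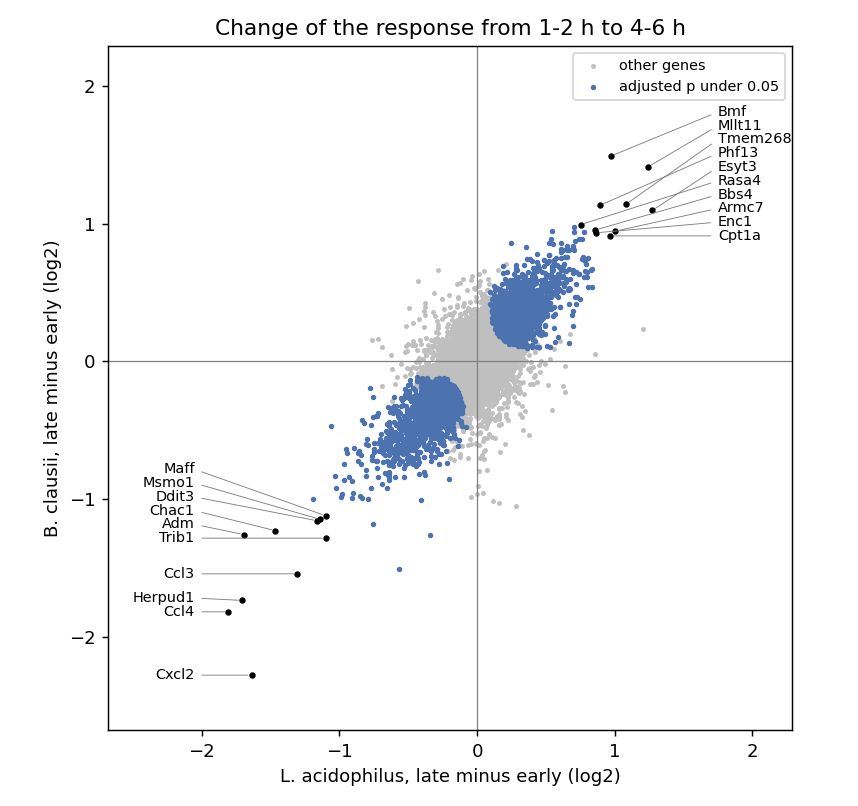
Change of the log2 ratio from 1 and 2 h to 4 and 6 h with L. acidophilus (x axis) and with B. clausii (y axis), 1 point per gene, with genes past adjusted p 0.05 in blue and the named genes in black. Over all genes r was 0.74, against 0.501 simulated for shared untreated pools with no effect and equal variances. The 3639 called genes run from Cxcl2 at the lower left to Bmf and Mllt11 at the upper right. Their place along the diagonal follows from the selection, since disagreement between the bacteria is the spread of the fit.

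ER chaperone genes fell together from early to late times. Of 17, 0 rose, 13 fell (Herpud1, Dnajb9 by 0.67 ± 0.07, Manf and Edem1) and 4 did not pass, with the same counts adjusted over the list alone (mean -0.47, adjusted p = 6.58e-09, and adjusted p = 0.245 with an estimated correlation). Cholesterol synthesis genes fell as well, 14 of 24, with Msmo1, Ebp (-0.92 ± 0.13) and Dhcr7 (-0.79) in front, 0 rises and 10 not passed, and the same counts adjusted over the list alone (mean -0.36, adjusted p = 1.78e-06, and adjusted p = 0.599 with an estimated correlation). Protease and coagulation genes had 0 rises, 6 falls (Adamts1 -0.82, Plaur -0.60 and Plau -0.54 among them) and 4 not passed, with the same counts adjusted over the list alone (mean -0.34, adjusted p = 3.57e-04, and adjusted p = 0.337 with an estimated correlation). Integrated stress response genes had 1 rise, 9 falls (Chac1, Ddit3, Ddit4 at -0.76 and Vegfa at -0.70) and 9 not passed, or 1 and 10 adjusted over the list alone (mean -0.31, adjusted p = 7.69e-04, and adjusted p = 0.337 with an estimated correlation). Hypoxia and glycolysis genes had 0 rises, 13 falls (P4ha1 -0.99, Slc2a1 -0.91, Ndrg1 -0.80 and Ankrd37 -0.77) and 11 not passed, with the same counts adjusted over the list alone (mean -0.29, adjusted p = 9.09e-04, and adjusted p = 0.443 with an estimated correlation). These first lists kept their calls in 23 of 24 alternatives each.

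Immediate early genes moved both ways. Maff, Klf2 (-1.04 ± 0.18) and Ier5 (-0.61) fell and Fos rose (0.78 ± 0.06), and of 21 genes 3 rose, 8 fell and 10 did not pass, with the same counts adjusted over the list alone (mean -0.22, adjusted p = 0.0145, and adjusted p = 0.646 with an estimated correlation). Chemokine genes had 0 rises, 5 falls (Cxcl2, Ccl4, Ccl3, and Ccl2 at -0.80 ± 0.19 among them) and 6 not passed, or 1 and 5 adjusted over the list alone (mean -0.59, adjusted p = 0.0198, and adjusted p = 0.599 with an estimated correlation). Macrophage identity genes had 1 rise, 5 falls and 10 not passed, or 2 and 7 adjusted over the list alone (mean -0.20, adjusted p = 0.046, and adjusted p = 0.646 with an estimated correlation), with the interferon regulatory factor gene Irf8 at -0.88, Lyz2 at -0.60, Cd14 at -0.49 and Cd68 at -0.47. The chemokine call ended without the 6 h B. clausii array (adjusted p = 0.0590), both 2 h arrays (0.0656) or with a normexp offset of 0 (0.0597), and the immediate early call without the 1 h B. clausii array (0.0506), both 1 h arrays (0.104) or with the processed signals (0.0728). The identity call ended without the L. acidophilus array of 2 h (0.0715) or 6 h (0.305), the B. clausii array of 1 h (0.0506) or 4 h (0.121), both 2 h arrays (0.0989) or both 6 h arrays (0.210), with a normexp offset of 0 (0.0699), and with the stricter filter on dim probes (0.134), which ended the immediate early call too (0.0989). In all 4 comparisons the series matrix values ended the same list calls as the processed signals.

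**Figure D3:**
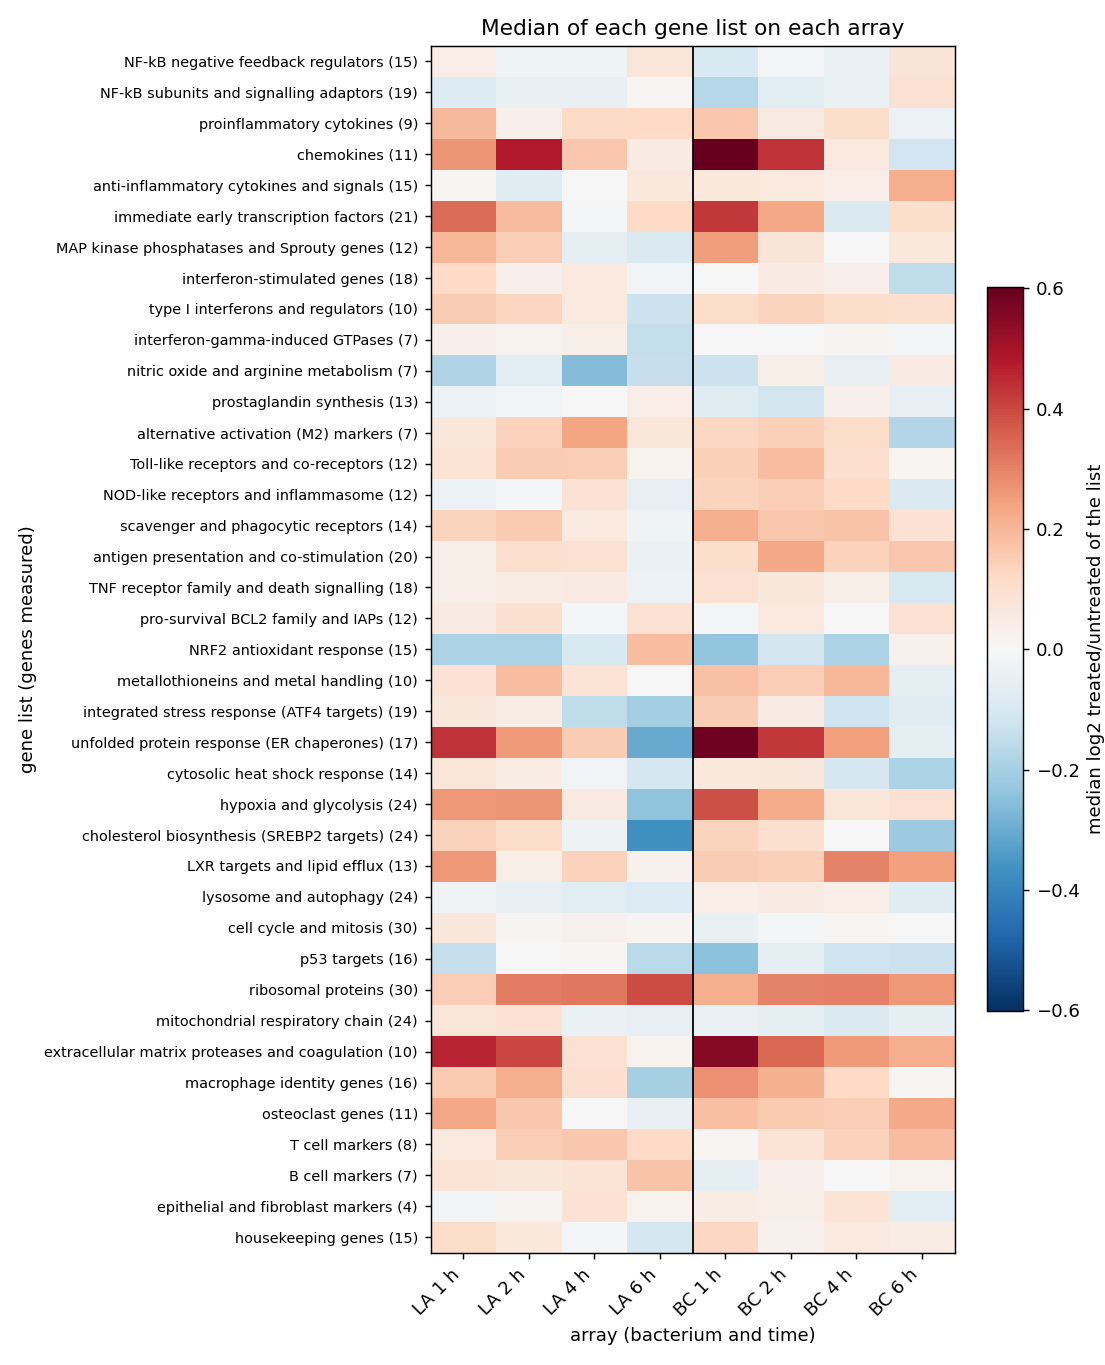
Median log2 ratio of treated to untreated cells of each of the 39 gene lists tested (vertical axis) on each of the 8 arrays (horizontal axis, LA for L. acidophilus and BC for B. clausii, with the hour). The ER chaperone list runs from 0.43 at 1 h to -0.30 at 6 h with L. acidophilus and from 0.59 to -0.06 with B. clausii, and the cholesterol synthesis list from 0.14 to -0.37 and from 0.13 to -0.22.

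Whether the time course differed between the bacteria was asked with the interaction of bacterium and phase, early or late. Ccl2 stood at 1.37, 1.78, 1.19 and 1.27 at 1, 2, 4 and 6 h with L. acidophilus and at 1.48, 1.42, 0.49 and -0.11 with B. clausii, and Ccl7 at 0.77, 1.23, 0.84 and 1.24 against 1.17, 0.92, 0.31 and -0.12. Their interaction values of 0.92 and 0.99 did not pass (adjusted p = 1.00 each), and neither did those of Syt12 (0.58), Tmem150a (0.54), Plb1 (0.51), Zfp97 (-0.80), Tenm2 (-0.68), Olfr295 (-0.56), Igkv2-112 (-0.56) and H2-Ob (-0.54). This fit took the times of a phase as replicates and did not pair the arrays of a time. Limma called 0 genes, with 176 at an unadjusted p under 0.05, and paired by time, with 2 residual degrees of freedom, it called 0 with 517. It called 0 also with a robust prior and intensity trend or with the processed signals. Without the B. clausii array of 2, 4 or 6 h it called 3, 8 and 1 genes, without both 4 h arrays 16 and without both 6 h arrays 1.

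Of the fixed panel of 25 macrophage genes, 18 were measured. Il1b, Il6, Il12b, Nos2, Ifnb1, Ifit1 and Arg1, among them the best-known inflammatory cytokine genes, were on the array but not well above background. With L. acidophilus Ccl2, Cxcl2, the NF-kB inhibitor gene Tnfaip3 (0.40 ± 0.04, adjusted p = 3.53e-04), the itaconate synthase gene Acod1 (0.36 ± 0.07, adjusted p = 0.0055) and Cxcl10 (0.29 ± 0.04, adjusted p = 0.00108) rose, and these calls held whichever array or time was left out, with Acod1 at 0.21 at its lowest. Tnf (0.23), Ccl3 (0.25), Ccl4 (0.17), Cd40 (0.14), Tlr2 (0.13) and Socs3 (0.27) passed as rises and the cyclooxygenase gene Ptgs2 (-0.32 ± 0.05) and Ccl5 (-0.15) as falls. Each of these depended on which arrays were kept. Tnf was lost without the L. acidophilus array of 2 or 4 h or both 4 h arrays (adjusted p up to 0.131), Ptgs2 without both 2 h arrays (0.0754), and Socs3 without the L. acidophilus array of 4 or 6 h or both arrays of those times (up to 0.202). Ccl3 was lost without the L. acidophilus array of 2, 4 or 6 h or both arrays of 1 or 2 h (up to 0.864), and Ccl5 without the L. acidophilus array of 1, 2 or 4 h or both arrays of 1, 2 or 6 h (up to 0.219). Ccl4 was lost without the L. acidophilus array of 1 or 4 h or both 2 h arrays (up to 0.301), and turned to -0.20 without both 1 h arrays. Cd40 and Tlr2 were lost without any of the L. acidophilus arrays of 1, 2 and 4 h, without the 4 h B. clausii array or both 4 h arrays, and Cd40 further without the 2 h B. clausii array or both 2 h arrays (up to 0.248) and Tlr2 without the 6 h L. acidophilus array or both 6 h arrays (up to 0.311). Il10 (-0.10), Il1rn (0.01), Cd14 (-0.08), Nfkbia (0.13) and Hmox1 (-0.10) did not pass.

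With B. clausii, Tnfaip3 (0.49 ± 0.04, adjusted p = 8.27e-05), Ccl2 (0.82 ± 0.13, adjusted p = 0.00148), Cd40 (0.28) and Cxcl10 (0.27) rose and Ptgs2 fell (-0.54 ± 0.05, adjusted p = 1.19e-04), as did the heme oxygenase gene Hmox1 (-0.27, adjusted p = 0.00268), and all of these calls held whichever array or time was left out. So did that of Tnf (0.42 ± 0.05, adjusted p = 4.36e-04), which median centring turned to -0.02. Across those omissions Tnf ranged from 0.31 to 0.65 and Hmox1 from -0.44 to -0.17. Cxcl2 (0.55), Ccl4 (0.26) and Cd14 (0.23) passed too, but Cxcl2 and Ccl4 stood at -0.05 and -0.09 without both 1 h arrays, were lost without both 2 h arrays as well (adjusted p up to 0.521 and 0.998), and Cd14 was lost there (0.0688), and median centring turned Ccl4 to -0.19 and Cd14 to -0.17. Il10 (-0.09), Il1rn (-0.09), Ccl3 (0.05), Ccl5 (-0.11), Tlr2 (0.10), Nfkbia (0.11), Socs3 (0.08) and Acod1 (0.19) did not pass. No panel gene differed between the bacteria in the limma contrast, where Cd14 (-0.31, adjusted p = 0.0707), Cxcl2 (0.58, adjusted p = 0.129) and Ccl2 (0.58, adjusted p = 0.138) had the largest differences or lowest p.

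Between early and late times Cxcl2, Ccl4 and Ccl3 fell whichever array was left out, and Ccl2 (-0.80), Cd14 (-0.49), Nfkbia (-0.43) and Tnfaip3 (-0.23) also passed as falls, against rises of Ptgs2 (0.50), Tnf (0.44), Hmox1 (0.36), Tlr2 (0.30) and Cd40 (0.23). Tnf, Ptgs2 and Ccl2 were lost without both 2 h arrays (adjusted p up to 0.639, 0.222 and 0.0687), Ptgs2 also without both 6 h arrays, and Ccl2 without the 4 h L. acidophilus array or the B. clausii array of 1, 2 or 4 h. Hmox1 (up to 0.849) and Tlr2 (up to 0.0835) were lost without both arrays of 1 h or of 6 h, Cd14 without both 6 h arrays (0.0697), and Nfkbia without the 2 h L. acidophilus array, the 4 h B. clausii array or both 6 h arrays (up to 0.0740). Tnfaip3 and Cd40 kept their calls in 4 and 3 of 12 such fits. Both were lost without the L. acidophilus array of 2 or 4 h, any B. clausii array, or both arrays of 1 or 6 h, and Cd40 without both 4 h arrays (up to 0.834 for Tnfaip3, which stood at 0.03 without both 1 h arrays, and 0.216 for Cd40).

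**Figure D4:**
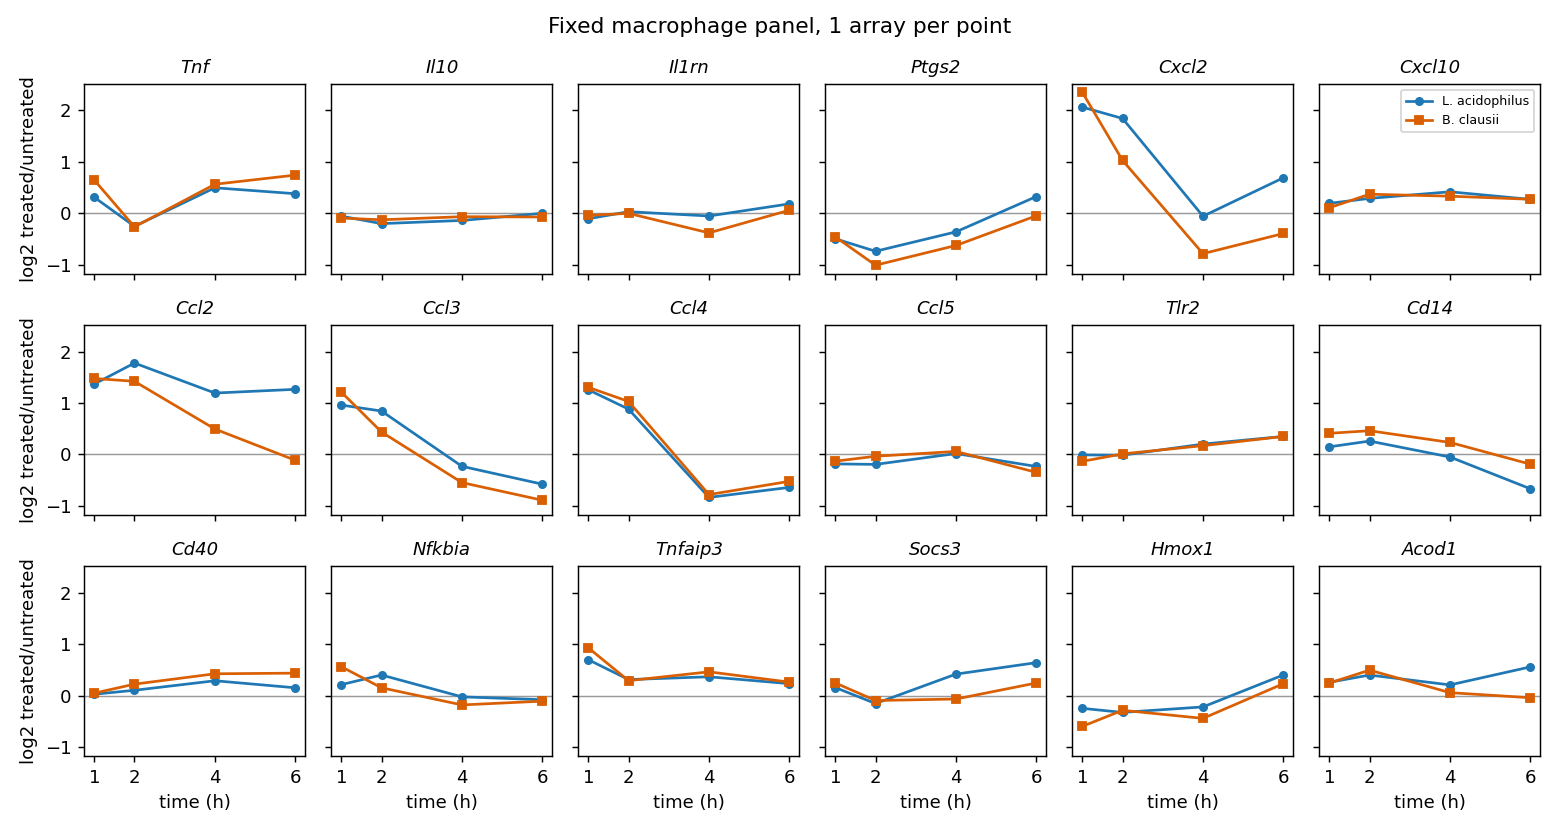
Log2 ratio of treated to untreated cells (vertical axis) at 1, 2, 4 and 6 h (horizontal axis) for the 18 measured panel genes, with 1 line per bacterium and 1 array per point. Cxcl2 runs from 2.06 to 0.69 with L. acidophilus and from 2.35 to -0.39 with B. clausii.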

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

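Of the tests with a written prediction, those of untreated RNA and of drift in the untreated cells were chosen after the result was seen. The others were written before it. No prediction was written for the exchanges within times, the splits with times kept together, the overlap of called genes or the spike-in controls.

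The response differed between the bacteria in 95 genes and 7 lists, of which 0 lists were called with an estimated correlation. Slide and scan may have produced this, and with 0 slides that hold arrays of both bacteria this cannot be told apart from an effect of the bacterium. Probe GC content is less likely as the cause of most calls, since 59 of 95 genes stayed past the threshold after a GC correction. The median difference stayed at 0.43 for those higher with L. acidophilus and went from -0.38 to -0.37 for those lower. Over all genes, however, the difference had a Spearman correlation of -0.22 with probe GC. The 29 lower genes had a median GC of 50%, against 43.3% for all genes. A part of GC in the calls that were lost was not excluded. A difference in untreated RNA alone is also less likely, since in 94 of 95 genes the treated channel had the sign of the ratio. For genes higher with L. acidophilus the median difference was 0.36 in the treated and -0.11 in the untreated channel. For those lower it was -0.38 and 0.09. The genes were chosen on the ratio, however, which favours such a sign, and the treated channel alone called 0 genes. A part of the untreated RNA was therefore not excluded. Chance could not be excluded: in a model with the split alone, 2 of 35 splits of the arrays called at least 4 genes, the real one (4) and the split by early and late times (1179), which is the highest other and points to a structure of the samples, while the 8 exchanges within times (95 against at most 0) were too few to judge.

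Between early and late times 3639 genes and 8 lists differed, with 0 lists called with an estimated correlation. Position on the slide may be the cause and cannot be told apart from time, with 0 positions that hold more than 1 time. A drift of the untreated cells is less likely for most of these genes, as 87.9% changed more in the treated than in the untreated channel, although Ccl3 changed more in the untreated one. Genes higher late had a median change of 0.28 in the treated and -0.04 in the untreated channel, and genes lower late -0.33 and -0.01. That share was not computed over all genes, whose treated channel varied more as well (quartiles -0.16 to 0.13 against -0.09 to 0.05). The genes were also chosen on the ratio, so a part of such a drift was not excluded. Among 35 splits that treat all arrays as exchangeable only 1, the real one, called 1179 genes, and the highest other called 4. With the arrays of a time kept together 3 splits remain, 1179 against at most 0, which are too few to judge chance.

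Both bacteria shifted 4002 genes in the same direction, with 0 dye-exchanged arrays to test whether dye bias may account for them. A gene-specific dye effect and a shared response therefore cannot be told apart for any gene called only in the mean responses. Of these genes, 30.3% also changed between early and late times, against 22.5% of the others, and a constant dye effect would cancel in that contrast. Both calls use the same spread of each gene, however, so genes with a small spread pass in both. The overlap therefore cannot decide on dye bias.

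The spike-in controls differed by 0.449 log2 between the arrays of the bacteria. This could come from unequal amounts of control RNA, from the slides or from a difference in the RNA content of the cells, and scaling to the controls raised the number of genes that differ from 95 to 14422. The sources used here do not give the amounts added, so no test separates these causes.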

How the results depend on the processing

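The settings with local background as deposited, with scaling to spike-in controls and with time as a block in the interaction were chosen after the result was seen. No paired analysis by replicate number was possible because each bacterium and time has 1 array of pooled RNA, although time entered as a block in every limma comparison but the interaction, and slide could not enter as a block because it coincides with the bacterium. The cause was not tested for any result that moved. Genes below background in either channel limit the counts, since an array detects at most about 51.5% of probes in a channel. The 111 called results of named and panel genes had 2814 values under other settings, of which 2303 kept the call, 503 lost it and 8 had the opposite sign. The 25 called list shifts had 607, of which 488 kept the call, 118 lost it and 1 had the opposite sign. These settings overlap, so the shares kept do not measure how firm the calls are. An adjusted p under 0.1 cannot lose a gene call, and the processed signals and the series matrix hold nearly the same values. Between the bacteria, leaving out either or both arrays of a time gives the same estimates. Among results not called, 55 gene and 51 list values passed under another setting.

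Against 95 genes that differ between the bacteria, the count was 0 with the processed signals, the series matrix values, offset 0 or the treated channel alone, 21 without background correction, 25 without the filter on dim probes, 261 with the strict filter, 4 without the time term, 237 with a trended robust prior, 525 at adjusted p under 0.1, 9 with the local background as deposited, 4935 with median centring and 14422 with spike-in scaling. The share of these genes higher with L. acidophilus, 69.5%, was 98.3% with median centring, 85.7% without background correction, 84.0% without the filter, 88.9% with the local background as deposited and 0.083% with spike-in scaling, but 53.6% with the strict filter, 55.7% with a trended robust prior and 52.0% at adjusted p under 0.1. The genes changed by L. acidophilus (6247) were 3057 without the time term and 2329 with the local background as deposited, those changed by B. clausii (6541) were 3448 and 3586, and the share that rose fell from 56.2% to 22.9% and from 52.2% to 8.85% with median centring, and was 45.2% and 38.4% with the local background as deposited. Early against late, 3639 genes became 1303 with the processed signals, 1301 with the series matrix, 2249 with offset 0 and 1328 with the local background as deposited, and the share that rose, 49.8%, became 88.3% with median centring and 66.6% with spike-in scaling. The interaction kept 0 genes with time as a block.

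The number of lists called, old or new, went from 3 to 1 for L. acidophilus with the processed signals, the series matrix or no time term, and from 7 to 2 with the processed signals or the series matrix and 4 with median centring for B. clausii. Between the bacteria it went from 7 to 4 without the time term and to 1 with spike-in scaling, a list not among the 7. The shifts of the 7 over other genes stayed the same with spike-in scaling. An estimated correlation gave 0 lists in every comparison. Fry, which does not compare a list with other genes, called 23, 21, 2 and 16 lists, and its mixed form 38, 37, 23 and 37. The genes at least 2-fold away from 0 at 1, 2, 4 and 6 h were 636, 433, 427 and 719 with L. acidophilus and 1015, 690, 714 and 877 with B. clausii with the processed signals, 634, 430, 425 and 715, and 1014, 685, 714 and 875 with the series matrix, and 143, 97, 104 and 246, and 279, 131, 177 and 343 with offset 0. At 3-fold they were 3, 2, 0 and 0, and 5, 0, 2 and 3. Median centring gave 1952, 131, 80 and 284 with B. clausii, scaling between arrays 42 at 2 h with B. clausii, the mean over probes 28 at 6 h with L. acidophilus and 22 and 45 at 4 and 6 h with B. clausii, and local background as deposited 10 at 1 h with L. acidophilus and 9 at 2 h with B. clausii.

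Median centring reversed, in the mean response to B. clausii, Tnf (-0.0162), Ccl3 (-0.41), Ccl4 (-0.19), Tlr2 (-0.34), Cd14 (-0.17), Nfkbia (-0.31), Socs3 (-0.38) and Acod1 (-0.26), and the ER chaperone list between the bacteria (0.0283). Spike-in scaling moves every gene by the same 0.449 between the bacteria and so reversed, with no bearing on these genes in particular, Il1rn (-0.34), Ptgs2 (-0.23), Cxcl10 (-0.43), Ccl3 (-0.25), Tlr2 (-0.42), Nfkbia (-0.43), Socs3 (-0.27), Hmox1 (-0.27) and Acod1 (-0.28). Leaving out both arrays of a time, Ccl4 ranged from -0.199 (without 1 h) to 0.499 (without 4 h) with L. acidophilus, with -0.0733 without 2 h, and from -0.0913 (without 1 h) to 0.604 (without 4 h) with B. clausii. Cxcl2 ranged from -0.0509 (without 1 h) to 0.995 (without 4 h) and Ccl3 from -0.334 (without 1 h) to 0.367 (without 6 h) with B. clausii, and Tnfaip3 from -0.483 (without 2 h) to 0.0293 (without 1 h) from early to late.

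Leaving out arrays gave 3237 to 6941 genes for L. acidophilus (4095, 3583 and 3237 without its 1, 2 and 4 h arrays) and 3953 to 7152 for B. clausii (4198 and 3953 without its 2 and 4 h arrays). Between the bacteria it gave 15, 0, 0 and 3 without 1, 2, 4 and 6 h. Early against late it gave 1141 to 4057, with 1766 and 1782 without the 2 and 4 h L. acidophilus arrays, 2163, 2108 and 1909 without the 1, 2 and 4 h B. clausii arrays, and 1141 and 1197 without both 1 h and both 6 h arrays. The interaction had 0 to 16 genes, with 3, 8 and 1 without the 2, 4 and 6 h B. clausii arrays, 16 without both 4 h arrays and 1 without both 6 h arrays. Lists numbered 4 and 3 for B. clausii without both 1 h and both 2 h arrays, and 5 for L. acidophilus without both 6 h arrays.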

Other observations

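No test in this part was chosen after the result was seen, apart from the choice of what to describe.

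Several gene groups that might be looked for after bacteria did not pass in camera in any comparison, and the lowest adjusted p of each is given here. The comparisons average over several times, so a shift at a single time is not excluded. The list of MAPK phosphatases and Sprouty genes had a median of 0.20 at 1 h and -0.09 at 6 h with L. acidophilus. With B. clausii it stood at 0.25 and 0.07. Proinflammatory cytokine genes (9 measured) had 3 rises, among them Ltb (0.99), with B. clausii (adjusted p = 0.208). NF-kB feedback genes (15) moved both ways, with Tnfaip3 at 0.40 and Traf1 at -0.75 with L. acidophilus (lowest adjusted p = 0.486, between the bacteria), and NF-kB subunits and adaptors (19) had 6 rises and 2 falls from early to late (0.258), with Ticam1 at -0.57. Anti-inflammatory genes (15) had 7 rises and 0 falls with B. clausii (0.180), with Il10ra at 0.36. Interferon-stimulated genes (18) had 1 rise and 4 falls from early to late (0.499), type I interferon pathway genes (10) reached 0.334 between the bacteria, and interferon-gamma-induced GTPases (7) had 1 fall from early to late (0.234). Toll-like receptor genes (12) had 1 rise and 5 falls from early to late (0.197), with Tlr7 at -0.39, NOD-like receptor genes (12) reached 0.486 between the bacteria, and MAPK phosphatases (12) had 3 rises and 6 falls from early to late (0.519), with Dusp4 at -0.97.

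NRF2 targets (15) came closest, with 2 rises and 8 falls with B. clausii (0.0647) and Sqstm1 at -0.29. Nitric oxide and arginine genes (7) had 2 rises and 4 falls with L. acidophilus (0.431), prostaglandin genes (13) 2 rises and 4 falls with B. clausii (0.382), and alternative activation markers (7) 1 rise and 2 falls from early to late (0.320). TNF receptor and cell death genes (18) reached 0.642 between the bacteria, pro-survival genes (12) 0.486 there, and p53 targets (16) had 4 rises and 8 falls with B. clausii (0.255), with Sesn1 at -0.55. Metallothionein and metal genes (10) had 5 rises and 2 falls with B. clausii (0.349), cytosolic heat shock genes (14) 3 rises and 7 falls there (0.360), with Hspa8 at -0.51, and osteoclast genes (11) 6 rises and 1 fall there (0.120), with Oscar at 0.58. Lysosome genes (24) had 3 rises and 5 falls from early to late (0.197), with Ctss at -0.48. Cell cycle genes (30) reached 0.476 and mitochondrial genes (24) 0.299 between the bacteria.

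As lists from other cell types, T cell genes (8) had 5 rises and 0 falls with L. acidophilus (0.200), with Lck at 0.28, B cell genes (7) 2 rises and 0 falls there (0.431), and epithelial and fibroblast genes (4) 0 rises and 0 falls in every comparison (0.751 from early to late). Housekeeping genes (15) reached 0.183 between the bacteria. Neutrophil markers were not tested, as too few were measured. The 25 list shifts called in the 4 comparisons had the same sign in mean, median and test. In 17 other cases, none of them called, the signs differed: with L. acidophilus the NOD-like, TNF receptor, heat shock, lysosome, mitochondrial and housekeeping lists, with B. clausii the NF-kB feedback, interferon-stimulated, alternative activation and stress response lists, between the bacteria the NF-kB subunit, immediate early, nitric oxide, prostaglandin and metallothionein lists, and from early to late the anti-inflammatory and cell cycle lists.

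Arrays far apart in time and bacterium correlated weakly across genes, with r of 0.19 for 1 h L. acidophilus against 6 h B. clausii and 0.08 for 1 h B. clausii against 6 h L. acidophilus. Within a bacterium 1 h and 6 h gave 0.29 and 0.14. Where called genes had several probes, all probes had the same sign in 55.8% (L. acidophilus), 58.5% (B. clausii), 73.3% (between the bacteria) and 59.6% (early to late) of them, so a value from the brightest probe does not always describe the gene.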
